A study of Homo sapiens with 54 samples.

How the data were processed

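U2OS cells received a control siRNA or 1 of 2 siRNAs against YTHDF2, and total cytoplasmic RNA was taken at 0, 0.5, 1, 2, 4 and 6 h. Per the labels' protocols, the RNA of each of the 18 cultures was sequenced as input and after m6A immunoprecipitation, as a bound fraction (m6A-IP) and a flow-through. This gave 54 libraries in 9 groups of 6 times. Reads were trimmed with Trim Galore, aligned with Bowtie2 and quantified with RSEM 1.3.0 on genome build hg19, per the submitters' processing notes. The versions of Trim Galore and Bowtie2 and the transcript annotation are not given in the sources used here. The authors deposited TPM (transcripts scaled to a fixed total) in a single table for 52000 isoforms in 54 sample columns, all of which were used. TPM keeps no read number, so the depth of each library and the precision it gives are unknown. How transcription was stopped is not given in the sources used here either.

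From the deposited TPM, isoforms were summed per gene, which gave 26409 genes. Of 5121 isoforms without a gene symbol 4910 were named through their accession, as were 72 of 74 whose symbol had become a calendar date. The 213 left unnamed held between 0.0164% and 1.15% of TPM and were not tested as genes. The TPM of ribosomal RNA, 7SL, 7SK, RMRP, RPPH1 and small nucleolar RNAs stayed in the denominator and is given as a share of each library. No pair of libraries was identical, and the highest correlation between any pair was 0.991.

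Libraries were grouped by the siRNA and fraction in their title. For 1 library the title names siRNA 1, flow-through, 6 h, while the treatment field names siRNA 2. It was placed by its title, and alternatives without it were run. YTHDF2 itself was read first in every library, as a check of the labels.

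Genes with a mean of at least 1 TPM over the libraries of a comparison were tested with limma-trend (limma 3.58.1, R 4.3.3) on log2(TPM + 1), 2-sided, and p-values were adjusted over genes by Benjamini and Hochberg. A gene was called at an adjusted p under 0.05. The effect of YTHDF2 siRNA in each fraction was the mean of both siRNAs against control with time as a block, and a call needed the same sign for each siRNA. Enrichment was m6A-IP against flow-through in control cells with time as a block. The change of that ratio with YTHDF2 siRNA was an interaction with the 18 RNA samples as a block. Slopes were straight lines on hours, in control input, as m6A-IP minus flow-through in control cells, as YTHDF2 siRNA minus control in each fraction, and as the difference of that change between m6A-IP and flow-through. This makes 11 comparisons. Residual degrees of freedom were 10 for each level comparison, 5 for enrichment, 15 for the change of ratio, 12 for control input slopes, 8 for the slope difference in control, 12 for each change of slope and 24 for the last. The 6 times stand in for repeats.

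Because TPM sum to a constant, a change in abundant noncoding RNA moves every mRNA. Gene values in the report are therefore relative to the median gene, from the same test after each library was rescaled so that the median log2 value of the tested genes was equal. That median was taken before the pseudocount of 1 TPM was added. A relative value is therefore not simply the deposited value minus the median change. Counts on TPM as deposited, the scale of the planned test, are given beside them. Standard errors are those of limma. SD is given for levels in TPM.

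Gene lists were tested with camera in limma with a preset correlation of 0.01 and again with a correlation estimated from the residuals. The second result is given wherever it changed a call. Of 21 lists, 19 had members in the tests: immediate early and unstable mRNAs, G2 and M phase, S phase, cholesterol synthesis, deadenylation and decapping (decay factors), unfolded protein response, glycolysis, interferon response, known YTHDF2 targets (target controls), m6A readers, m6A writers and erasers, nuclear RNA, nuclear-encoded oxidative phosphorylation, p53 targets, replication histones, ribosomal proteins, secreted and matrix proteins, snoRNA hosts and C2H2 zinc fingers. Mitochondrial mRNAs were not in the table, and markers of other cell types had at most 1 member tested. List members were also counted after adjusting p over the list alone.

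The genes named in the text follow a rule: in each comparison, up to 12 with the largest positive and 12 with the largest negative change among called genes with a mean of at least 5 TPM, for siRNA effects with the same sign in at least 5 of 6 times with each siRNA, up to 4 members of each list with the smallest p, and YTHDF1, YTHDF2, YTHDF3, SON, CREBBP, MYC, MALAT1 and GAPDH. Exceptions are stated where they are named. The groups, tests, thresholds, lists, this rule and the main alternatives were fixed before the data were examined. Alternatives for the values relative to the median gene were chosen after seeing the data.

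Shares, correlations and slopes between quintiles over the 6 times were tested by exact permutation of the 720 orders of times or by exact sign flips, 2-sided, where 0.03125 is the smallest p possible. Agreement between the siRNAs was set against 100 simulated sets of unchanged groups that share their control. Counts of calls were set against 100 regroupings of the libraries or orders of the times, or for enrichment all 32 swaps of the fraction labels within times. Each test was first tested on simulated data with 200 changed genes. In these, camera found 10 of 10 raised lists of 30 genes and called 1 of 10 unchanged ones, or 0 of 10 with an estimated correlation. The simulated noise was drawn separately for each gene and library, with no correlation between genes and no difference between courses. Its shares of false calls are therefore not the error rate of the real data.

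Alternatives were a pseudocount of 0.1 TPM, no filter, scaling to the median gene or to the median ribosomal protein gene, isoforms tested one by one, robust variance estimates, leaving out each time, models with or without the block, each siRNA alone, the square root of time, and leaving out the library with conflicting labels. Analyses ran in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9, and in R with the data.table package (version 1.17.8).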

Results

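RNA was sequenced from U2OS cells, a human osteosarcoma line, that had received a control siRNA or 1 of 2 siRNAs against YTHDF2. YTHDF2 is a cytoplasmic protein that binds N6-methyladenosine (m6A) in mRNA and recruits the deadenylation machinery. Total cytoplasmic RNA (input) was collected at 0, 0.5, 1, 2, 4 and 6 h, and m6A immunoprecipitation (m6A-IP) separated it into a bound, methylated fraction and an unmethylated flow-through. The 54 libraries form 9 groups of 6, with 1 library for each siRNA, fraction and time. No condition was repeated, so the 6 times stand in for repeats, and p-values measure only the spread between these libraries. Values were deposited as relative abundances that sum to the same total in each library (TPM), which keep no read number, so the depth of each library is unknown. Each library held between 999998 and 1000001 TPM over 52000 isoforms, of which 50.3% to 58.8% were listed at 0. How transcription was stopped is not given in the sources used here. A TPM slope is therefore a change of an RNA's share of its library, not an absolute decay rate.

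The libraries differed in their makeup by fraction and by siRNA. In control input, mRNA took 27.0% ± 5.09 of TPM (SD, n = 6 times), 7SL RNA 35.1% ± 4.96, 7SK RNA 10.5% ± 4.98 and ribosomal RNA 9.85% ± 4.32. In input of YTHDF2 siRNA 1 and siRNA 2, mRNA took 31.7% ± 3.54 and 32.9% ± 5.09. The m6A-IP removed 7SL RNA almost completely, to 0.0975% ± 0.0117 with control siRNA, and mRNA then took 85.6% ± 6.90 with control siRNA and 85.0% ± 6.64 with siRNA 2. In the siRNA 1 m6A-IP libraries mRNA took only 44.2% ± 16.7 and ribosomal RNA 52.8% ± 17.8, with a range of 23.7% to 77.3%. Over time, the mRNA share of siRNA 2 input fell from 38.2% at 0 h to 24.7% at 6 h, and 7SL RNA rose from 27.7% to 36.7%. In siRNA 2 flow-through 7SL RNA rose from 29.0% to 40.4% and RMRP with RPPH1 from 10.4% to 16.5%. Exact 2-sided permutation of the times gave p = 0.00139 for the first and p = 0.00278 for the other 3, and all 4 had an adjusted p of 0.0375 over the 54 share slopes tested. In siRNA 1 input the mRNA share went from 28.9% to 26.8% (exact permutation p = 0.372, adjusted p = 0.479). In control input the mRNA share went from 31.1% to 21.3%, with an exact permutation p of 0.00556 and an adjusted p of 0.05, which did not pass.

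**Figure D1:**
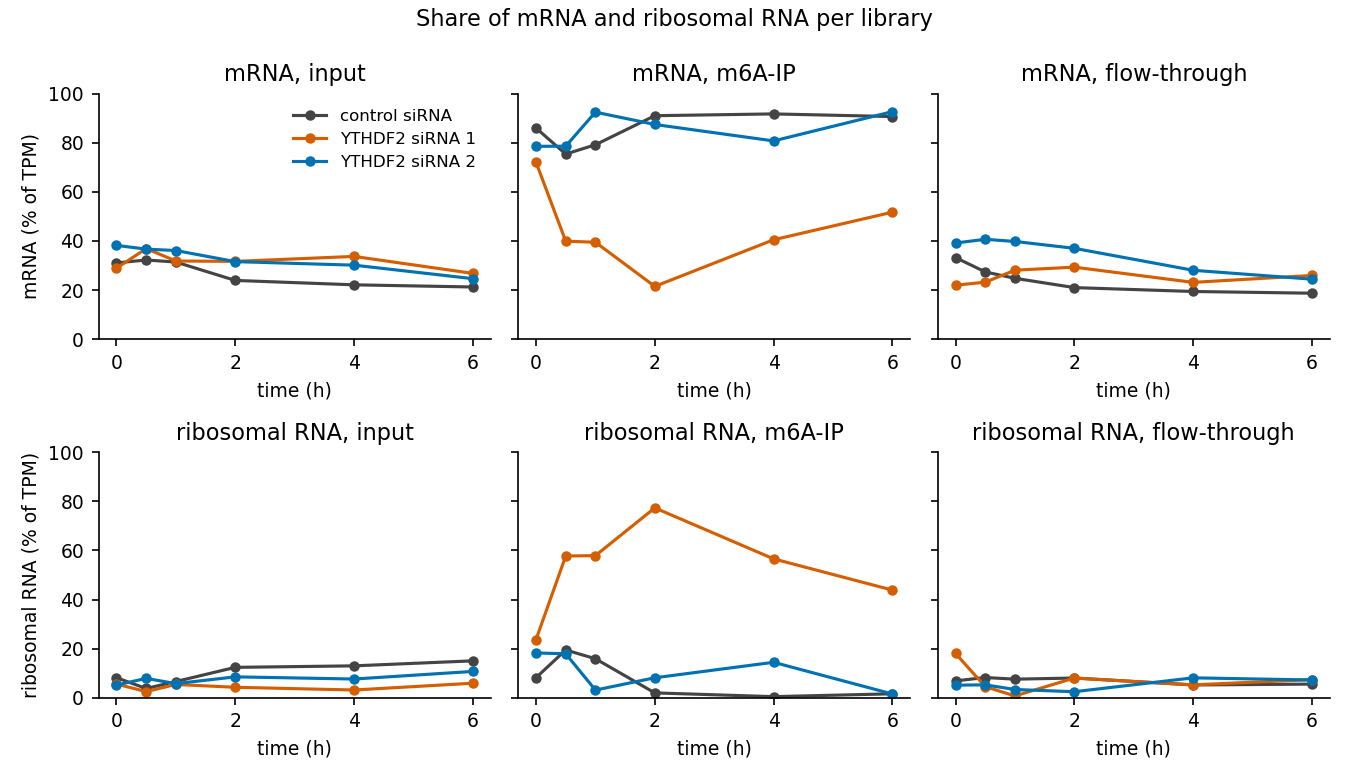
Share of TPM (percent) taken by mRNA (top) and ribosomal RNA (bottom) against time in hours, 1 point per library, for the 3 siRNAs in each fraction. Ribosomal RNA reaches 77.3% in the siRNA 1 m6A-IP library of 2 h, against at most 19.5% in the control m6A-IP libraries.

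YTHDF2 RNA was lower with both YTHDF2 siRNAs at each of the 6 times in all 3 fractions. In input it stood at 13.8 TPM ± 8.16 with control siRNA (SD, n = 6 times), 3.94 TPM ± 2.53 with siRNA 1 and 1.43 TPM ± 1.10 with siRNA 2. Relative to the control library of the same time, 28.0% ± 2.77 remained with siRNA 1 and 10.5% ± 3.16 with siRNA 2. In m6A-IP 12.3% ± 9.63 and 6.62% ± 2.81 remained, and in flow-through 47.1% ± 19.3 and 29.8% ± 16.8. YTHDF2 RNA itself was rich in the m6A-IP, at 214.4 TPM ± 74.97 with control siRNA against 3.01 TPM ± 1.93 in flow-through. The most abundant YTHDF2 isoform alone gave 13.5% and 1.59% remaining in input. With siRNA 2 this isoform stood at 1.57 TPM at 0 h and at 0 TPM at each later time. With siRNA 1 it ran from 0.05 to 3.73 TPM. These 2 means thus lie near the floor and are no measure of a stronger knockdown. YTHDF2 was called in the gene tests of all 3 fractions, with log2 changes relative to the median gene of -2.33 ± 0.10 in input, -3.13 ± 0.17 in m6A-IP and -1.13 ± 0.10 in flow-through (SE). The last is compressed, because the level lay near the pseudocount of 1 TPM.

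**Figure D2:**
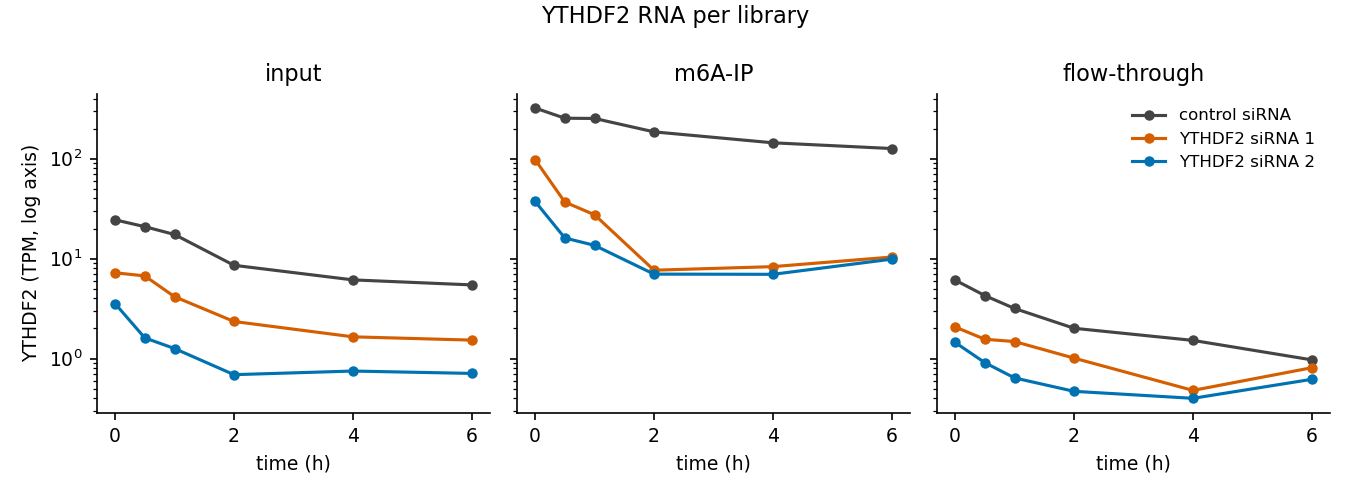
YTHDF2 RNA (TPM, log axis) against time in hours, 1 point per library, for the 3 siRNAs in each fraction. Input levels ran from 5.46 to 24.5 TPM with control siRNA, from 1.53 to 7.22 TPM with siRNA 1 and from 0.69 to 3.55 TPM with siRNA 2.

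The effect of YTHDF2 siRNA on total cytoplasmic RNA was asked first. Relative to the median gene, CTGF fell by 2.65 ± 0.13 on the log2 scale (SE, n = 6 times for each siRNA), from 65.1 TPM ± 31.5 with control siRNA to 17.81 TPM ± 12.01 with siRNA 1 and 10.3 TPM ± 8.65 with siRNA 2. CTGF and CYR61, which fell by 1.69 ± 0.05, encode secreted matricellular proteins and are classical targets of the YAP and TEAD factors. The stress cytokine gene GDF15 fell by 1.97 ± 0.17, the death receptor gene TNFRSF10B by 1.45 ± 0.08, and the glucose transporter gene SLC2A3 by 1.87 ± 0.11. Among the largest increases were KRT17, a keratin, at 1.67 ± 0.07, AP2A1, a subunit of the clathrin adaptor AP-2, at 1.46 ± 0.08, and SFN (14-3-3 sigma), at 1.21 ± 0.06. Of the decay factors, the decapping enzyme gene DCP2 rose by 1.06 ± 0.08. YTHDF3, a paralog of YTHDF2, rose by 0.45 ± 0.06, with 0.27 for siRNA 1 and 0.62 for siRNA 2. YTHDF1 was at -0.10 ± 0.04 and was not called.

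Genes of the cholesterol synthesis list fell as a group in input: 17 of 20 fell and 0 rose, with a median of -0.42. INSIG1, which holds back activation of the sterol-responsive transcription factors, fell by 1.03 ± 0.10. Among 24 S phase genes 19 rose and 1 fell, with a median of 0.38. They included the replicative helicase genes MCM3 (0.75 ± 0.06) and MCM2 (0.65 ± 0.06), the clamp loader RFC2 (0.53 ± 0.04) and the transcription factor E2F1 (0.58 ± 0.06). Of 21 secreted and matrix genes 14 fell and 3 rose, among them SERPINE2, a protease inhibitor, which fell by 1.92 ± 0.07, and IGFBP3, which fell by 1.28 ± 0.09. IGFBP3 fell mostly with siRNA 2, to 2.82 TPM ± 0.231, against 9.53 TPM ± 2.01 with siRNA 1 and 11.35 TPM ± 1.78 with control siRNA. Tenascin TNC rose with siRNA 1 by 1.56 and stood at 0.06 with siRNA 2. In the unfolded protein response list 10 of 19 genes fell, with PDIA4 at -1.29 ± 0.07 and the pro-apoptotic factor DDIT3 at -0.82 ± 0.12. The fall of PDIA4 was larger with siRNA 1, at 51.0 TPM ± 6.76, than with siRNA 2, at 115.5 TPM ± 9.80, against 147.8 TPM ± 11.2 with control siRNA. Ribosomal protein genes had 23 of 79 members that fell and 1 that rose, but 26 that rose and 0 that fell on deposited TPM. Replication histones had 5 of 27 that rose. The counts adjusted over the list alone were the same for these 6 lists.

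The 6 lists passed camera, a gene set test in limma that sets a list against the other genes. Cholesterol genes had an adjusted p of 1.33e-05 and 0.00693 with an estimated correlation. The other 5 did not hold with an estimated correlation. S phase had an adjusted p of 1.55e-05, and adjusted p = 0.605 with an estimated correlation. Ribosomal proteins had 1.33e-05, secreted and matrix genes 0.000155, the unfolded protein response 0.00123 and histones 0.00589, each with adjusted p = 0.759 with an estimated correlation. On TPM as deposited the cholesterol genes also lost their call, at adjusted p = 0.765 with an estimated correlation. On that scale the splits were 3 up and 9 down for cholesterol, 21 up and 0 down for S phase, 22 up and 0 down for histones, 3 up and 8 down for secreted genes, and 3 up and 7 down for the unfolded protein response. The ribosomal protein median changed sign, from 0.17 on deposited TPM to -0.18 relative to the median gene.

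The remaining lists did not pass in input. Interferon-stimulated genes had 10 of 22 that rose and 4 that fell, with ISG20, an exonuclease, at 0.83 ± 0.06 and the ISG15 ligase HERC5 at 0.76 ± 0.05. Immediate early genes had 6 of 34 that rose and 13 that fell, with IER3 at -1.21 ± 0.10 and FOSB at 1.16 ± 0.12. FOSB stood at 0.202 TPM ± 0.142 with control siRNA, 4.04 ± 2.60 with siRNA 1 and 0.967 ± 0.847 with siRNA 2. Its rise was thus larger with siRNA 1, and is compressed by the pseudocount of 1 TPM. Decay factors had 9 up and 7 down of 27, G2 and M phase genes 3 up and 10 down of 28, nuclear-encoded oxidative phosphorylation subunits 13 up and 24 down of 63, and glycolytic enzymes 7 up and 3 down of 18, or 8 up and 3 down adjusted over the list alone, with a median of 0.11 and a mean of -0.0041. The p53 targets had 4 up and 5 down of 21, with a median of 0.05 and a mean of -0.11. The m6A writers and erasers had 2 up and 3 down of 11, the m6A readers 2 up and 1 down of 10, snoRNA hosts 2 up and 4 down of 15, nuclear-retained RNAs 0 up and 4 down of 7, and zinc finger genes 25 up and 49 down of 182, or 24 up and 47 down adjusted over the list alone. Of the 4 transcripts taken here as YTHDF2 target controls, 2 fell: SON by 0.25 ± 0.06 and the nuclear RNA MALAT1 by 1.11 ± 0.13. YTHDF2 is cytoplasmic, so MALAT1 is a doubtful control. MYC (0.10 ± 0.08) and CREBBP (0.14 ± 0.07) were not called. The fall of SON held on 1 scale only, since on deposited TPM it stood at 0.08 and was not called. On deposited TPM the splits were 13 up and 0 down for interferon genes, 13 and 5 for immediate early genes, 19 and 1 for decay factors, 12 and 1 for G2 and M phase, 37 and 1 for oxidative phosphorylation, 14 and 1 for glycolysis, 11 and 2 for p53 targets, 8 and 0 for writers and erasers, 8 and 1 for readers, 6 and 1 for snoRNA hosts, 2 and 2 for nuclear RNAs, 74 and 5 for zinc fingers and 2 and 1 for the target controls. The directions of the G2 and M phase, oxidative phosphorylation, snoRNA host, immediate early, zinc finger, writer and eraser, p53 target and target control lists thus depended on the scale. GAPDH was at 0.19 ± 0.06 and not called, with -0.02 for siRNA 1 and 0.41 for siRNA 2. Of the mitochondrially encoded mRNAs none of the 13 was in the table, and of 12 markers of other cell types 0 were tested in input and 1 in m6A-IP.

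In input 5571 of the 10595 genes tested with limma were called relative to the median gene, 2881 up and 2690 down. On deposited TPM 6785 were called, 6007 up and 778 down, with the median gene shifted by 0.29, and 3659 genes were called with the same sign on both scales. A call needed the same sign for each siRNA, but each siRNA alone called 6136 and 6593 genes relative to the median gene, and 6382 genes differed between siRNA 1 and siRNA 2. Leaving out 1 time at a time gave 5006 to 5606 calls. In simulated data with 200 changed genes, 59.7% of changes of 0.3, 89.6% of 0.5 and 98.5% of 1 (log2) were recovered in this comparison, and 1.79% of calls were false. The simulated data here and below had no correlation between genes and no difference between courses. The share of false calls in the real data can therefore be higher.

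The 2 siRNAs share the control libraries, so their changes correlate with no effect at all. Across genes, which are not independent replicates, the changes of siRNA 1 and siRNA 2 relative to the median gene had r = 0.464 in input, 0.466 in m6A-IP and 0.564 in flow-through. Simulated unchanged groups gave 0.496, 0.497 and 0.501. The covariances were 0.0913, 0.125 and 0.117 against simulated values of 0.0107, 0.0188 and 0.0109. The excess holds what the siRNAs share and also any lasting difference of the 1 control course, so it measures neither alone. With the control times split into separate sets for each siRNA, r was 0.361 and 0.442 in input, 0.360 and 0.395 in m6A-IP and 0.426 and 0.512 in flow-through. The changes of both siRNAs had the same sign in 66.2% of genes in input, 65.0% in m6A-IP and 67.6% in flow-through, where the shared control alone gave 66.7%, 66.6% and 66.7% in simulated data. Shared sign was thus about as frequent as a shared control alone gives. Each siRNA called 1750 genes up and 1654 down in input alike, and 812 in opposite directions. These numbers were 1696, 1567 and 775 in m6A-IP and 1831, 1543 and 822 in flow-through. Independent lists would share 985.7 up and 922.8 down in input, 894.5 and 834 in m6A-IP and 1114 and 813.8 in flow-through, but lists with a shared control are not independent, so the excess is no measure of a shared effect.

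**Figure D3:**
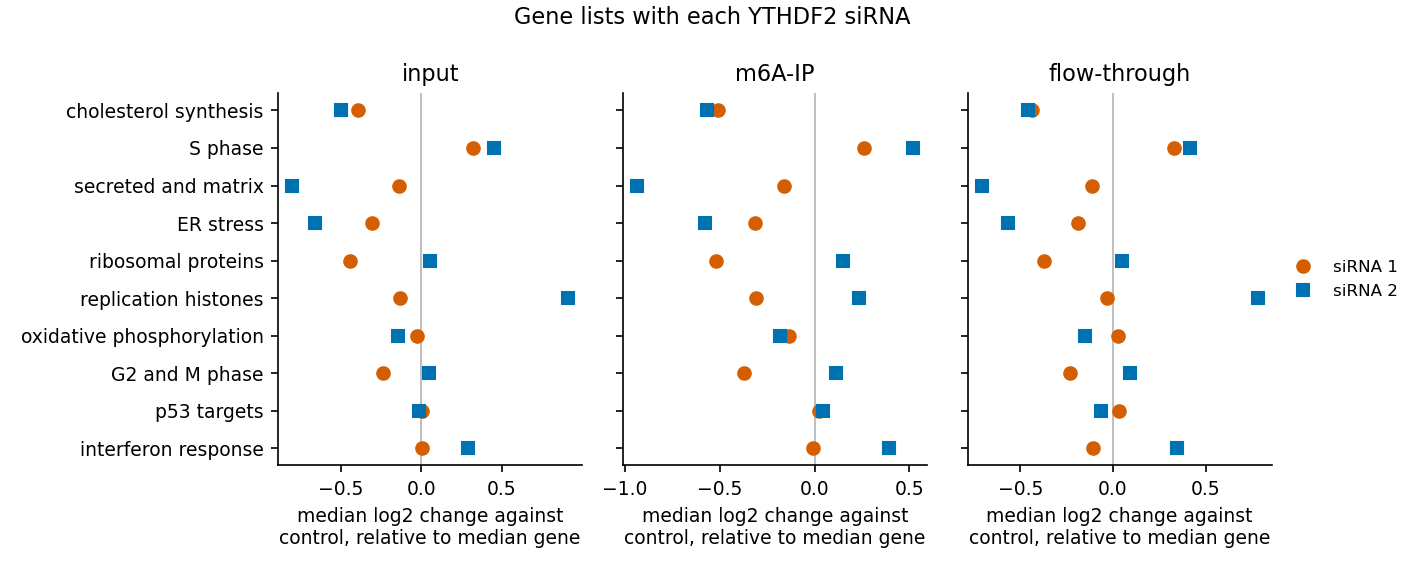
Median log2 change against control siRNA, relative to the median gene, of 10 gene lists with siRNA 1 (circles) and siRNA 2 (squares) in each fraction. Cholesterol genes lie at -0.39 and -0.50 in input and S phase genes at 0.32 and 0.45, while ribosomal proteins (-0.44 and 0.05, with 0.17 for both together on deposited TPM) and replication histones (-0.13 and 0.91) have opposite signs with the 2 siRNAs.

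List medians were also compared between the siRNAs. Cholesterol genes were called down by both siRNAs separately in 13 of 20 cases in input, 13 of 20 in m6A-IP and 15 of 20 in flow-through, and S phase genes were called up by both in 15, 12 and 14 of 24. Ribosomal protein genes in input had medians of -0.44 with siRNA 1 and 0.05 with siRNA 2 (0.17 for both on deposited TPM), replication histones -0.13 and 0.91, and secreted and matrix genes -0.14 and -0.80. Camera on the difference between the siRNAs gave p = 1.18e-19, p = 6.94e-08 and p = 4.53e-06 for these 3 lists, and p = 0.0506, p = 0.180 and p = 0.208 with an estimated correlation. Other differences had p under 0.05 with an estimated correlation: snoRNA hosts in input (p = 0.0364, medians -0.34 and 0.10) and in m6A-IP (p = 0.0275, -0.50 and 0.12), G2 and M phase genes in m6A-IP (p = 0.0155, -0.37 and 0.11) and zinc finger genes in flow-through (p = 0.00825, -0.07 and 0.11). Adjusted over the 19 lists of each fraction, none held, the lowest being adjusted p = 0.452 in input, 0.261 in m6A-IP and 0.157 in flow-through.

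In the m6A-IP fraction, the question was how methylated RNA changed. The chemokine receptor gene CCR1 fell by 3.31 ± 0.17 relative to the median gene (SE, n = 6 times for each siRNA), from 22.3 TPM ± 5.04 to 1.01 TPM ± 1.26 with siRNA 1 and 1.01 TPM ± 0.375 with siRNA 2. CTGF fell by 2.75 ± 0.12, SLC2A3 by 2.09 ± 0.11, GDF15 by 1.95 ± 0.15, SERPINE2 by 1.73 ± 0.08 and TNFRSF10B by 1.53 ± 0.09. The immediate early gene FOSB rose by 2.44 ± 0.17, with 3.50 for siRNA 1 and 1.38 for siRNA 2, the guanine nucleotide exchange factor gene MCF2L by 2.07 ± 0.07 and AP2A1 by 1.52 ± 0.10. YTHDF3 rose by 0.61 ± 0.05. With both siRNAs CCR1 lay near the pseudocount of 1 TPM, so its fall is compressed. In input CCR1 was lower too, at 1.08 TPM with control siRNA, 0.0933 with siRNA 1 and 0.0383 with siRNA 2. MCF2L was higher there, at 0.705, 4.09 and 3.62 TPM. Levels in m6A-IP alone thus do not separate a change of methylation from a change of abundance. Of the 4 target controls, MYC rose by 0.31 ± 0.06 and CREBBP by 0.47 ± 0.09 while MALAT1 fell by 1.22 ± 0.18 and SON (-0.17 ± 0.07) was not called. Adjusted over the list alone, 2 rose and 2 fell, with a median of 0.07 and a mean of -0.15. On deposited TPM, MYC stood at -0.14, CREBBP at 0.04 and YTHDF3 at 0.16, and none of these 3 was called.

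Cholesterol genes fell in the m6A-IP too, 16 of 20 with 1 rise (17 and 1 adjusted over the list alone), with the sterol pathway enzyme genes SC5D at -1.05 ± 0.13 and MSMO1 at -1.02 ± 0.15, and INSIG1 at -1.16 ± 0.15. Camera gave an adjusted p of 3.56e-05, and 0.0092 with an estimated correlation, but on deposited TPM the call was lost at adjusted p = 0.999 with an estimated correlation. The other lists past camera did not hold with an estimated correlation. S phase genes had 15 of 24 that rose and 0 that fell, against 1 up and 2 down on deposited TPM, with MCM2 at 1.41 ± 0.20, and adjusted p = 0.542 with an estimated correlation. Secreted and matrix genes had 14 of 21 that fell and 3 that rose, with IGFBP3 at -1.35 ± 0.07, and the unfolded protein response had 10 of 20 that fell and 1 that rose, with PDIA4 at -1.15 ± 0.07 and XBP1 at -0.91 ± 0.08. Both had adjusted p = 0.542 with an estimated correlation. Ribosomal proteins had 21 of 79 that fell and 4 that rose, with RPS29 at -1.21 ± 0.15, and adjusted p = 0.672 with an estimated correlation. Mean deposited TPM of RPS29 was 360 with control siRNA, 51.8 with siRNA 1 and 259 with siRNA 2, and that of PDIA4 1054, 147 and 847. The counts adjusted over the list alone were the same for these last 4 lists. On deposited TPM the splits were 0 up and 17 down for cholesterol, 1 up and 18 down for secreted genes, 0 up and 15 down for the unfolded protein response and 0 up and 17 down for ribosomal proteins. The S phase median changed sign, from -0.02 on deposited TPM to 0.41.

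Of 12501 genes tested in m6A-IP, 5693 were called relative to the median gene, 2932 up and 2761 down, and leaving out 1 time at a time gave 5122 to 5549. On deposited TPM 4432 were called, 170 up and 4262 down, with the median gene shifted by -0.39. That shift was -0.85 with siRNA 1, whose libraries held the most ribosomal RNA, and 0.08 with siRNA 2. In simulated data 29.9% of changes of 0.3, 71.6% of 0.5 and 95.5% of 1 were recovered, and 4.38% of calls were false.

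In the flow-through, the unmethylated fraction, KRT17 rose by 1.74 ± 0.06 (SE, n = 6 times for each siRNA), from 14.7 TPM ± 4.28 to 72.2 TPM ± 11.5 with siRNA 1 and 59.9 TPM ± 9.63 with siRNA 2. AP2A1 rose by 1.47 ± 0.07 and YTHDF3 by 0.48 ± 0.08. CTGF fell by 2.43 ± 0.14, GDF15 by 1.92 ± 0.16, SERPINE2 by 1.87 ± 0.06 and TNFRSF10B by 1.43 ± 0.08. The U1 spliceosomal RNA RNU1-1 fell by 2.91 ± 0.60 and SNORA71D, a guide for RNA pseudouridylation, fell by 3.19 ± 0.75. In input SNORA71D stood at 37.9 TPM ± 21.7 with control siRNA, 7.66 ± 9.88 with siRNA 1 and 97.4 ± 50.8 with siRNA 2. RNU1-1 stood there at 242 TPM ± 258, 83.0 ± 85.8 and 230 ± 96.5. With siRNA 2 the input thus did not show these falls. RNU1-1 has near-identical copies among which reads can be split, so its value is uncertain. Of the target controls MYC rose by 0.25 ± 0.05 and CREBBP by 0.29 ± 0.06, while SON fell by 0.30 ± 0.06 and MALAT1 by 1.00 ± 0.11. On deposited TPM SON stood at 0.05 and was not called.

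Cholesterol genes fell in the flow-through in 18 of 20 cases with 0 rises (18 down and 1 up adjusted over the list alone), with MSMO1 at -1.21 ± 0.08 and INSIG1 at -1.04 ± 0.12. Camera gave an adjusted p of 2.02e-06, and 0.041 with an estimated correlation, but on deposited TPM the call was lost at adjusted p = 0.974 with an estimated correlation. S phase genes had 18 of 24 that rose and 1 that fell, with the flap endonuclease gene FEN1 at 0.79 ± 0.06, MCM3 at 0.67 ± 0.05 and E2F1 at 0.51 ± 0.05. The unfolded protein response had 10 of 19 that fell and 0 that rose, with PDIA4 at -1.31 ± 0.07, and both lists had adjusted p = 0.715 with an estimated correlation. PDIA4 stood at 102.6 TPM ± 14.7 with control siRNA, 31.9 ± 3.58 with siRNA 1 and 90.6 ± 12.8 with siRNA 2. Secreted and matrix genes had 13 of 20 that fell and 3 that rose, with adjusted p = 0.773 with an estimated correlation. Ribosomal proteins had 28 of 79 that fell and 0 that rose, against 22 up and 1 down on deposited TPM, and histones 8 of 27 that rose (6 adjusted over the list alone). For both, adjusted p = 0.785 with an estimated correlation. HIST1H4E stood at 0.11 with siRNA 1 and 1.32 with siRNA 2, and reads of histone genes can be split between near-identical copies. On deposited TPM the splits were 2 up and 7 down for cholesterol, 21 up and 0 down for S phase, 3 up and 3 down for the unfolded protein response, 3 up and 7 down for secreted genes and 16 up and 0 down for histones.

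Of 9737 genes tested in flow-through, 5327 were called relative to the median gene, 2949 up and 2378 down, and leaving out 1 time at a time gave 4951 to 5191. On deposited TPM 6003 were called, 5409 up and 594 down, with the median gene shifted by 0.34. In simulated data 74.6% of changes of 0.3, 91.0% of 0.5 and all of 1 were recovered, and 4.32% of calls were false. The 6 h library of siRNA 1 has a title naming siRNA 1 and a treatment field naming siRNA 2, and was placed by its title. Without it 5533 genes were called on deposited TPM.

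Which RNAs the m6A-IP enriched was tested in the 6 control pairs of m6A-IP and flow-through. The noncoding RNA LINC00473 was enriched by 4.51 ± 0.08 over the median gene (log2, SE, n = 6 times), the atypical cadherin gene FAT1 by 4.25 ± 0.09, the proliferation marker MKI67 by 4.17 ± 0.11 and the kinetochore gene CENPF by 4.12 ± 0.08. FAT1 stood at 845 TPM ± 270 in m6A-IP and 5.63 TPM ± 1.58 in flow-through. The target controls were all enriched, SON by 3.58 ± 0.09, MYC by 2.86 ± 0.07, CREBBP by 2.25 ± 0.09 and MALAT1 by 0.70 ± 0.07. So were the reader genes YTHDF3 (3.33 ± 0.07), YTHDF2 (3.28 ± 0.06) and YTHDF1 (1.32 ± 0.06). In flow-through MKI67 (1.66 TPM ± 0.568, SD), YTHDF3 (1.48 TPM ± 0.584) and CREBBP (1.32 TPM ± 0.675) lay near the pseudocount of 1 TPM, so these 3 values are compressed, as are those of other genes at a few TPM or less. The strongest depletion was of RN7SL1, the RNA of the signal recognition particle, at -11.39 ± 0.25, and of RMRP, the RNA of RNase MRP, at -10.79 ± 0.21. Among mRNAs, the ribosomal protein genes RPS2 (-6.94 ± 0.07) and RPLP1 (-6.36 ± 0.07), the ATP synthase gene ATP5G2 (-6.74 ± 0.10) and GAPDH (-5.03 ± 0.05) were the most depleted named.

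By group, zinc finger genes were enriched in 295 of 325 cases and depleted in 20, with a median of 1.59, and ZNF41 (3.95 ± 0.07) and ZNF266 (3.92 ± 0.08) were among those with the smallest p. In flow-through these 2 stood at 0.205 TPM ± 0.109 and 0.490 TPM ± 0.1898 (SD), below the pseudocount of 1 TPM, so their values are compressed. Immediate early genes had 31 of 37 enriched and 5 depleted, with IER2 at 2.56 ± 0.09 and TNFAIP3, an inhibitor of NF-kB signalling, at 2.24 ± 0.07. The m6A writers and erasers had 9 of 11 enriched and 1 depleted, with the methyltransferase complex members RBM15 at 3.47 ± 0.08 and ZC3H13 at 3.01 ± 0.12, the second again compressed at 0.370 TPM ± 0.132 in flow-through. All 79 ribosomal protein genes were depleted, with a median of -3.92, and so were all 63 oxidative phosphorylation genes, with -2.71, although 20 of these rose and 17 fell on deposited TPM. Glycolytic enzymes had 15 of 18 depleted and 2 enriched (9 up and 3 down on deposited TPM), and snoRNA hosts 12 of 15 depleted and 3 enriched, with GAS5 at -4.70 ± 0.08. S phase genes had 21 of 24 depleted (21 up and 0 down on deposited TPM) and 2 enriched, FEN1 (3.05 ± 0.06) and MCM3 (0.62 ± 0.05). G2 and M phase genes had 21 of 28 depleted and 4 enriched (24 up and 1 down on deposited TPM), cholesterol genes 14 of 20 and 4 (15 up and 2 down), and replication histones 23 of 27 and 0 (13 up and 2 down). Lists that did not pass were split: decay factors 9 up and 16 down, the unfolded protein response 10 and 8, interferon genes 12 and 11 with IFIT1 at 3.59 ± 0.11 (compressed too, at 0.188 TPM ± 0.182 in flow-through), readers 5 and 5, p53 targets 8 and 11, secreted genes 11 and 10, and nuclear RNAs 4 and 3 with a median of 0.32 and a mean of -2.61. For every list here the counts adjusted over the list alone were the same.

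Camera called 12 of these lists and none held with an estimated correlation. The values with an estimated correlation were adjusted p = 0.0931 for oxidative phosphorylation and for S phase, 0.103 for glycolysis, 0.138 for snoRNA hosts, 0.2 for zinc fingers, 0.205 for ribosomal proteins and for writers and erasers, 0.283 for cholesterol, 0.34 for immediate early genes, 0.385 for the target controls and 0.741 for histones and for G2 and M phase. Enrichment is relative to the median gene, which itself rose by 2.21 on deposited TPM, because the m6A-IP removed most noncoding RNA. On that scale 11125 of 12122 genes were called, 10561 up and 564 down, against 10997 relative to the median gene, 5482 up and 5515 down. On deposited TPM ribosomal proteins split 9 up and 57 down, snoRNA hosts 4 and 6, zinc fingers 324 and 0, and immediate early genes 37 and 0. Leaving out 1 time at a time gave 10836 to 10956 calls.

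Whether YTHDF2 siRNA changed the ratio of m6A-IP to flow-through was tested as an interaction. YTHDF2 itself fell by 1.57 ± 0.21 in this ratio (SE, n = 6 times for each siRNA). In flow-through it stood at 3.01 TPM ± 1.93 with control siRNA, 1.235 ± 0.577 with siRNA 1 and 0.748 ± 0.386 with siRNA 2. These lie near the pseudocount of 1 TPM, which compresses the flow-through change and so enlarges the fall of the ratio. TGFA, a ligand of the EGF receptor, fell by 0.81 ± 0.12, but stood at -0.44 and was not called with a pseudocount of 0.1 TPM. The histone gene HIST2H2AC fell by 0.87 ± 0.17, but stood at -0.55 and was not called with siRNA 2 alone, and the caution on histone copies applies. XBP1, the transcription factor of the unfolded protein response, fell by 0.37 ± 0.07, and without 2 h it stood at -0.33 and lost its call. None of MYC (0.05 ± 0.10), CREBBP (0.10 ± 0.11), SON (0.17 ± 0.12), MALAT1 (-0.19 ± 0.15), YTHDF1 (0.10 ± 0.07), YTHDF3 (0.04 ± 0.08) and GAPDH (0.20 ± 0.07) was called. Immediate early genes had 3 of 37 that fell and 1 that rose (7 and 1 adjusted over the list alone), and histones 1 of 27 that fell and 0 that rose. Both passed camera, at adjusted p = 0.0194 and 0.0108, and both were lost at adjusted p = 0.917 with an estimated correlation. Their medians were -0.14 and -0.42. None of the other 17 lists tested passed.

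In all, 905 of 12053 genes were called relative to the median gene, 554 up and 351 down. On deposited TPM 9063 were called, 45 up and 9018 down, with the median ratio shifted by -0.72. Tested alone, but with the spread of the libraries of both siRNAs and control, siRNA 2 called 52. The 905 calls rested on single times: without 0.5 h 308 were called, without 1 h 546, without 2 h 213 and without 4 h 303. With the pseudocount at 0.1 TPM, 568 were called. In simulated data 20.9% of changes of 0.3, 59.7% of 0.5 and 95.5% of 1 were recovered, but 12 calls, or 9.30%, were false.

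Loss of RNA over time was followed first in control input, as a straight line of log2 TPM on hours relative to the median gene. Of the replication histone mRNAs, which are known to be short-lived outside S phase, 26 of 27 fell and 0 rose, with a median of -0.85 per h. As a list they passed camera but did not hold, at adjusted p = 0.314 with an estimated correlation. HIST1H3B changed by -1.10 ± 0.15 per h (SE, n = 6 times), HIST1H4H by -0.85 ± 0.08 and HIST1H4C by -0.40 ± 0.03, with the same caution on copies. Immediate early genes had 20 of 34 that fell and 0 that rose (26 and 0 adjusted over the list alone), a median of -0.25, and the transcription regulators MYC (-0.40 ± 0.07), ID3 (-0.42 ± 0.07) and KLF4 (-0.39 ± 0.06) and the survival factor MCL1 (-0.29 ± 0.05) among them. The p53 targets had 7 of 21 that fell and 0 that rose, including the nuclease gene AEN (-0.23 ± 0.04) and the cell death gene BBC3 (-0.25 ± 0.05). In the unfolded protein response the pseudokinase gene TRIB3 fell (-0.32 ± 0.02), in a list that did not pass.

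Among the m6A readers, YTHDF1 fell (-0.16 ± 0.02 per h) and so did YTHDF2 (-0.22 ± 0.06), whose call was lost without 0.5 h (-0.21) and without 4 h (-0.21). YTHDF3 (0.01 ± 0.02) was not called, nor were SON (0.05 ± 0.03), CREBBP (-0.05 ± 0.02), MALAT1 (0.24 ± 0.12) and GAPDH (0.04 ± 0.02). Zinc finger genes had 44 of 182 that fell and 7 that rose (46 and 7 adjusted over the list alone), with ZNF668 at -0.21 ± 0.03. The m6A writers and erasers had 3 of 11 that fell and 0 that rose, with RBM15B at -0.13 ± 0.02 and WTAP at -0.15 ± 0.03. S phase genes had 4 of 24 that fell and 1 that rose (4 and 0 adjusted over the list alone), with the licensing factor CDT1 at -0.17 ± 0.03, and G2 and M phase genes 5 of 28 that fell and 3 that rose (6 and 3 adjusted over the list alone). Of 21 secreted and matrix mRNAs 12 rose and 0 fell relative to the median gene (17 and 0 adjusted over the list alone), but 0 of either on deposited TPM with a median of -0.01, and the list did not hold, at adjusted p = 0.435 with an estimated correlation. Of 63 oxidative phosphorylation genes 11 rose and 1 fell (5 and 1 adjusted over the list alone), against 0 up and 36 down on deposited TPM. Of 79 ribosomal protein genes 12 rose and 0 fell (1 and 0 adjusted over the list alone), against 0 up and 50 down on deposited TPM. The spliceosomal RNA RNU4-1 (0.45 ± 0.08) and the guide RNA SCARNA2 (0.42 ± 0.09) rose.

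Camera called 10 lists in control input. None held with an estimated correlation: adjusted p = 0.314 for histones and for p53 targets, 0.418 for writers and erasers, 0.435 for immediate early, zinc finger and secreted genes, 0.557 for oxidative phosphorylation, S phase and G2 and M phase, and 0.694 for ribosomal proteins. Of 10595 genes 2472 were called relative to the median gene, 1364 up and 1108 down. On deposited TPM 6110 were called, 26 up and 6084 down, with a median slope of -0.095 per h. The relative count moved with single times, to 1306 without 0 h, 1388 without 0.5 h, 1487 without 1 h and 835 without 4 h. In simulated data 40.3% of slopes of 0.1, 95.5% of 0.3 and 93.9% of 0.5 per h were recovered, but 7.83% of calls were false.

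Enrichment in the m6A-IP was set against the slope in control input. Across 10526 genes on deposited TPM, the control ratio of m6A-IP to flow-through and the control input slope had a Spearman rank correlation of -0.214 and a Pearson r of -0.194. Genes are not independent replicates, and the rank correlation was -0.147 without 0 h and -0.281 with a pseudocount of 0.1 TPM. By quintile of the ratio, from lowest to highest, the median relative slope was 0.036, 0.033, 0.025, 0.0085 and -0.011 per h. The highest minus the lowest was -0.046 (exact 2-sided permutation of the times, p = 0.025, adjusted p = 0.05 over 2 tests), and the rank correlation of the relative values -0.267 (exact permutation p = 0.175), so neither passed. The highest quintile passed camera downward (adjusted p = 3.08e-07), with adjusted p = 0.0644 with an estimated correlation. The lowest 2 quintiles passed upward (adjusted p = 0.00971 each), with adjusted p = 0.375 and 0.171 with an estimated correlation, so no quintile held. The libraries behind the ratio and the slope do not overlap, but they come from the same control cultures.

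**Figure D4:**
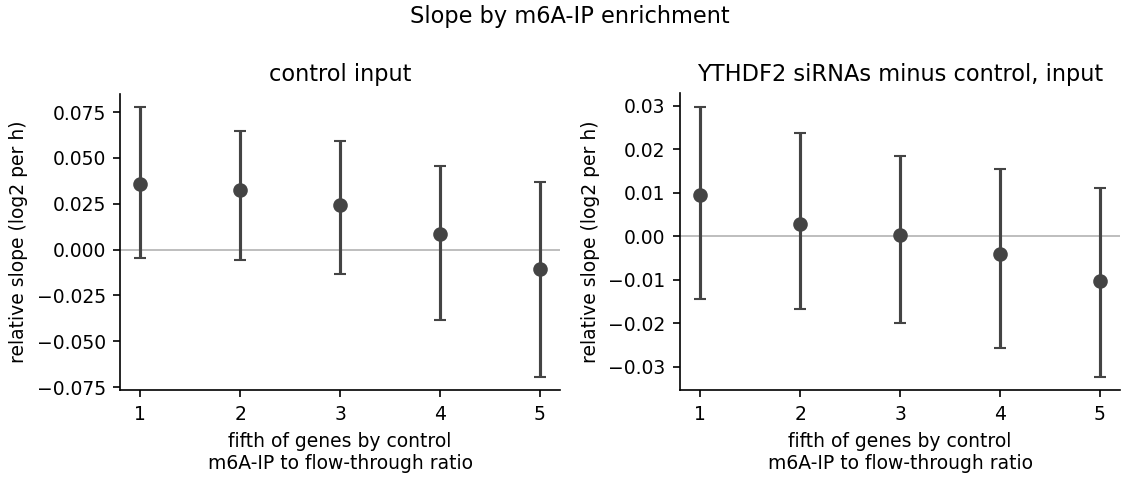
Median relative slope (log2 per h) of genes in each quintile of the control m6A-IP to flow-through ratio, in control input (left) and as the change with YTHDF2 siRNA in input (right), with bars from the 25th to the 75th percentile of genes. The medians run from 0.036 to -0.011 per h in control input and from 0.0094 to -0.010 per h for the change with siRNA.

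Methylated and unmethylated RNA of the control cells were compared by the difference of slopes, m6A-IP minus flow-through. Only 4 of 12122 genes were called relative to the median gene: the spliceosomal RNA RNU5A-1 (-1.25 ± 0.17 per h; SE, n = 6 times), the guide RNA SNORA65 (-0.96 ± 0.13), the chromatin regulator gene ASXL1 (-0.18 ± 0.02) and the centromere gene ITGB3BP (0.23 ± 0.03), each with an adjusted p of 0.045 in limma. RNU5A-1 stood at 0 TPM in all 6 control m6A-IP libraries, so its value is a rise in flow-through alone and says nothing of its methylated RNA. RNU5A-1, ASXL1 and ITGB3BP were chosen after their values were seen. No gene was called without 0, 0.5, 1, 4 or 6 h, and 1 was without 2 h. The test has no block for the RNA sample that both fractions share. With time as a block, 24 genes were called relative to the median gene, 14 up and 10 down, and 7521 on deposited TPM. With each time left out in turn the slopes ran from -1.09 to -0.89 for SNORA65, -0.19 to -0.17 for ASXL1 and 0.21 to 0.30 for ITGB3BP. MYC (-0.07 ± 0.12), SON (-0.09 ± 0.03), CREBBP (-0.08 ± 0.03) and YTHDF2 (-0.02 ± 0.03) were not called. Replication histones had 26 of 27 positive differences with a median of 0.36 and 12 up adjusted over the list alone, among them HIST1H2AG (0.71 ± 0.18) and HIST2H2AA3 (0.66 ± 0.17), neither called over all genes. Camera gave them an adjusted p of 1.14e-09, lost at adjusted p = 0.603 with an estimated correlation.

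Zinc finger genes were positive in 76 of 325 (median -0.047, adjusted p = 0.603 with an estimated correlation), ribosomal proteins in 8 of 79 (-0.043, adjusted p = 0.741 with an estimated correlation), nuclear RNAs in 1 of 7 (-0.090, adjusted p = 0.603 with an estimated correlation, 3 down adjusted over the list alone) and G2 and M phase genes in 23 of 28 (0.038, adjusted p = 0.712 with an estimated correlation). On deposited TPM 144 zinc finger, 79 ribosomal protein and 5 nuclear RNA members were positive. On that scale 6511 genes were called, 6312 up and 199 down, with a median difference of 0.14 per h, but 0 were called without 0.5 h and 2 without 4 h. At an unadjusted p under 0.05, 1456 genes passed relative to the median gene. In simulated data 7.46% of differences of 0.1, 73.1% of 0.3 and 89.4% of 0.5 per h were recovered, but 8.13% of calls were false.

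Without a block for time, no gene's slope was called as changed by YTHDF2 siRNA in any fraction, with either scaling. With time as a block, as in the comparisons of level, 8 genes were called in m6A-IP on deposited TPM (2 up and 6 down) and 2 in flow-through relative to the median gene (both down), and 0 in the others. In input the target controls stood at -0.11 ± 0.09 per h for MYC (SE, n = 6 times for each siRNA), -0.0028 ± 0.03 for CREBBP and -0.04 ± 0.03 for SON. The MYC value is imprecise, so a change of its slope is not excluded. The mitotic kinase gene PLK1 was at 0.10 ± 0.03, FEN1 at 0.08 ± 0.03 and the complex III subunit gene UQCRFS1 at 0.09 ± 0.03. In m6A-IP MYC was at -0.03 ± 0.09, CREBBP at 0.08 ± 0.03 and SON at -0.06 ± 0.03, with the AP-1 factor gene JUND at 0.20 ± 0.04 and adjusted p = 0.287. In flow-through MYC was at -0.04 ± 0.10, CREBBP at 0.05 ± 0.02 and SON at -0.07 ± 0.03, with CDC20, an activator of the anaphase-promoting complex, at 0.09 ± 0.02 and the interferon gene OAS3 at 0.06 ± 0.02. For the difference between m6A-IP and flow-through in the change with siRNA, MYC was at 0.01 ± 0.14, CREBBP at 0.01 ± 0.03, SON at 0.02 ± 0.05 and the ribosomal protein gene RPS16 at 0.26 ± 0.09.

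The limma count of 0 in input goes with 443 genes of 10595 at an unadjusted p under 0.05 relative to the median gene and 590 on deposited TPM. In m6A-IP these numbers were 852 and 114 of 12501, in flow-through 588 and 1407 of 9737, and for the difference between fractions 388 and 136 of 12053. Robust variance estimates in limma called 0, 1, 0 and 0 genes. Leaving out 1 time at a time gave up to 9 calls in m6A-IP (without 6 h) and up to 2 in flow-through (without 2 h), and 0 in the other 2 comparisons on deposited TPM. On deposited TPM the median slope change was 0.036 per h in input, -0.026 in m6A-IP, 0.059 in flow-through and -0.081 for the difference. With siRNA 1 it was 0.060 in input, -0.042 in m6A-IP and 0.114 in flow-through. With siRNA 2 it lay nearer 0, at 0.012, -0.010 and 0.0041. In simulated data 82.1%, 83.6%, 91.0% and 76.1% of changes of 0.3 per h were recovered, but only 34.3%, 11.9%, 32.8% and 7.46% of changes of 0.1 per h. False calls made up 8.05%, 4.51%, 5.23% and 8.06%. Changes of the size of the genes named here were thus mostly below what these libraries call.

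Camera called lists in the slope changes too, but none held with an estimated correlation and none of their members was called. Relative to the median gene, ribosomal protein genes had positive slope changes in 76 of 79 cases in m6A-IP (median 0.054 per h) and oxidative phosphorylation genes in 59 of 63 (0.046), while zinc finger genes had 82 of 336 (-0.038). In the difference between fractions the same lists had 77 of 79 (0.076), 56 of 63 (0.057) and 91 of 315 (-0.028). Camera gave adjusted p of 7.47e-10, 3.07e-06 and 3.13e-07 in m6A-IP and 1.32e-15, 4.54e-07 and 6.47e-07 for the difference. With an estimated correlation these were adjusted p = 0.598 in m6A-IP and 0.83 for the difference. On deposited TPM only 7 of 79 ribosomal protein genes and 5 of 63 oxidative phosphorylation genes were positive in the difference. In input 9 lists passed camera with medians between -0.065 and 0.053 per h, among them secreted and matrix genes (3 of 21 positive, 14 on deposited TPM), immediate early genes (7 of 34), snoRNA hosts (2 of 15, 11 on deposited TPM) and oxidative phosphorylation genes (45 of 63). Each had adjusted p = 0.715 with an estimated correlation. In flow-through snoRNA hosts (2 of 15 positive, median -0.049, but 0.029 on deposited TPM), ribosomal proteins (21 of 79, median -0.016, but 0.063 on deposited TPM) and immediate early genes (7 of 33) passed, with adjusted p = 0.549, 0.997 and 0.997 with an estimated correlation.

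Whether the change with YTHDF2 siRNA followed m6A enrichment was tested across genes at each time. The rank correlation between the control m6A-IP to flow-through ratio and the input change averaged -0.037 for siRNA 1 (SD 0.0875 over 6 times, 4 of 6 negative) and -0.062 for siRNA 2 (SD 0.042, 6 of 6 negative). Exact 2-sided sign-flip tests over the times gave p = 0.281 and p = 0.03125, the smallest that 6 times allow, with adjusted p of 0.281 and 0.0625 over the 2 siRNAs, so neither passed. The rank correlation ran from -0.123 to 0.0757 over the times for siRNA 1 and from -0.118 to -0.0137 for siRNA 2. For siRNA 1 the sign changed to 0.0156 among genes with a mean of at least 5 TPM. By quintile of the ratio, the highest had a median change in input of -0.05 relative to the median gene and an adjusted p of 0.196 in camera, and none of the 5 passed. The slope change with siRNA in input had a median of 0.0094 per h in the lowest quintile and -0.010 in the highest, which both passed camera at adjusted p = 0.00481. They did not hold at adjusted p = 0.506 and 0.324 with an estimated correlation.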

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

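The tests in this part were chosen after the results they bear on were seen, apart from the counts on deposited TPM with each siRNA alone, which were fixed before. Of 63 groups of 6 libraries checked, 6 had a library far from the other 5, where chance gives about 1 in 20 groups, or 3.15. That expectation holds for values without a trend, whereas each group here is a course over time. The excess is therefore no measure of faulty libraries. YTHDF2 RNA was highest at 0 h in siRNA 1 m6A-IP (98.1 TPM, the others 7.66 to 36.8), siRNA 2 m6A-IP (37.4 TPM, the others 6.97 to 16.1) and siRNA 2 input (3.55 TPM, the others 0.69 to 1.61). The 7SL share stood apart at 4 h in siRNA 1 m6A-IP (0.454%, the others 0.079% to 0.146%) and siRNA 2 m6A-IP (0.317%, the others 0.072% to 0.155%). The snoRNA share of control flow-through was lowest at 0 h, at 2.13% against 5.004% to 6.284%.

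The effects of the 2 siRNAs against the same control differed. With values relative to the median gene, 6382 genes differed between siRNA 1 and siRNA 2 in input, 6823 in m6A-IP and 6018 in flow-through, each by a limma test of the difference itself. The siRNA effect also differed between the m6A-IP and flow-through for 905 genes.

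Counts of calls were set against regroupings of the same libraries. For siRNA effects and ratio changes, 100 choices of which library of each time counts as control were used. The 2 swaps of whole courses were always among them, and the rest were drawn. In input the real count of 6785 on deposited TPM was reached by 1 of 100 groupings, itself, with 5172 the highest other. On the scale of the median gene 5571 was reached by 2 (highest other 5926) in input, 5693 by 3 (6347) in m6A-IP and 5327 by 2 (5725) in flow-through. In each case the others as large were swaps of whole courses. The drawn mixtures of courses thus did not reach these counts, but a difference between courses was not excluded. On deposited TPM 4432 was reached by 5 (10761) in m6A-IP and 6003 by 5 (6934) in flow-through, so chance was not excluded there. The 10761, more than 2 times the real count, came from the siRNA 1 course taken as control, and points to a structure of the samples, the makeup of that course, rather than to YTHDF2. For the ratio change 9063 was reached by 3 (10525, again the siRNA 1 course) and 905 by 2 (1036, the same course).

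For enrichment, 1 of 32 label swaps reached 11125 and 1 reached 10997 relative to the median gene, with 0 the highest other, so chance was excluded. Permuted times of control input reached 6110 in 1 of 100 (highest other 5995), and 2472 relative to the median gene in 2 (2991). Few orders reached the real counts, but another order exceeded the relative one, so chance is not excluded for this unrepeated course. For the slope difference between fractions in control cells, permuted times of the pairs reached 6511 in 2 of 100 (highest other 6637) and 4 relative to the median gene in 1 (2). Few orders reached the real counts, but another order exceeded the count on deposited TPM, and both counts rested on single times. Chance is thus not excluded for this unrepeated course. The slope changes with YTHDF2 siRNA had 0 calls, which all 100 groupings reach by definition, so nothing on chance follows. The highest others were 3567 in input, 1293 in m6A-IP, 6166 in flow-through and 1 for the difference.

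The first pattern weighed is the large number of genes called with YTHDF2 siRNA. With the siRNA 1 or siRNA 2 course in place of control, the fewer of both counts was 5136 in input, 5787 in m6A-IP and 4633 in flow-through, near the real counts. Differences between the 3 courses as such, for example separate transfections or harvests, could therefore give counts of this size, and the number of calls by itself is no measure of a YTHDF2 effect. The covariance of the contrasts with the control course set apart was 0.0913 in input, 0.125 in m6A-IP and 0.117 in flow-through. With siRNA 1 set apart it was 0.0955, 0.146 and 0.0686, and with siRNA 2 0.116, 0.142 and 0.114. Control thus had the lowest value in input and m6A-IP and the highest in flow-through. What stays open is which of the genes changed alike by both siRNAs depend on YTHDF2, since 1 control course served both.

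The second pattern is the lower ratio of m6A-IP to flow-through with YTHDF2 siRNA on deposited TPM. Ribosomal RNA in the siRNA 1 m6A-IP libraries may account for part of its calls. In this comparison siRNA 1 alone called 10773 genes and siRNA 2 alone, with less ribosomal RNA, 52. Both were tested with the spread of all 36 libraries, the variable siRNA 1 libraries among them. The 52 therefore does not show that siRNA 2 lacked the shift. A lower yield of most mRNAs in the m6A-IP without YTHDF2 cannot be told apart from differences in library makeup. With siRNA 2 the median ratio change averaged -0.378 (SD 0.137, negative at 6 of 6 times, exact 2-sided sign-flip p = 0.03125), but TPM holds no yield. Over the genes tested in each fraction, the median gene with siRNA 2 moved by 0.077 in m6A-IP and 0.508 in flow-through. With siRNA 1 these were -0.852 and 0.185. The lower ratio with siRNA 2 thus went with a higher flow-through, not a lower m6A-IP, on deposited TPM. A lower yield stays open, because the deposited values hold no yield. Whether an RNA standard was added before the immunoprecipitation is not given in the sources used here.

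The third pattern is the larger mRNA share of input with YTHDF2 siRNA, by 0.242 log2 with siRNA 1 and 0.290 with siRNA 2. With ribosomal RNA left out of the total it was still larger with siRNA 2, by 0.254 (SD 0.0836, positive at 6 of 6 times, exact 2-sided sign-flip p = 0.03125, adjusted p = 0.0469 over 3 tests). In these libraries less ribosomal RNA gave 0.0360 of the rise with siRNA 2. The 3 tests were siRNA 1, siRNA 2 and their mean, which repeats the other 2. The adjusted p is therefore not counted as passed. With siRNA 1 the rest was 0.158 (SD 0.208, positive at 5 of 6 times, exact p = 0.0938), so there less ribosomal RNA and another cause cannot be told apart, because the times spread more widely than the difference and the siRNA has 1 course. Slower loss of mRNA relative to 7SL RNA also stays open. mRNA over 7SL RNA was higher by 0.326 log2 on average (SD 0.256, positive at 5 of 6 times, exact 2-sided sign-flip p = 0.0625), but its slope difference of 0.0528 per h did not pass (exact 2-sided permutation p = 0.332). With siRNA 1 the mean difference was 0.233 (p = 0.219) and with siRNA 2 0.419 (p = 0.03125, adjusted p = 0.125, both exact), and the difference between the siRNAs was not beyond chance (exact p = 0.188).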

How the results depend on the processing

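Of 317 alternative values for the main results, 241 were counted as kept, 44 as weaker, 25 as stronger, 5 as moved and 2 as reversed. For counts of calls this compares only the number of calls, not which genes were called or their sign. Enrichment rescaled to the median gene counts as kept, with 10997 calls against 11125. Of these, 6043 were shared with the same sign and 4036 with the opposite sign. For siRNA effects in input, 5571 against 6785 calls also counts as kept, with 3659 shared of the same sign. The alternatives for values relative to the median gene were chosen after the results were seen, and the others before. For each change below whose alternative does not itself use fewer libraries, the cause was not tested. The 165 pairs of a named gene and a comparison had 2259 alternative values. Of these, 2171 stayed on their side of the threshold, with the sign compared only where both values were past it. A further 63 were no longer past the threshold and 17 were newly past it. Another 8 of opposite sign were newly past it, and 0 had opposite signs past it on each side. Depth is unknown, so what it limits could not be tested.

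Rescaled to the median gene or the ribosomal protein median, ratio changes fell from 9063 to 905 or 980, control slopes from 6110 to 2472 or 1326, and control slope differences from 6511 to 4 or 55. A pseudocount of 0.1 TPM gave 568 ratio changes and 0 slope differences relative to the median gene, and 4 slope changes in input on deposited TPM and 2 relative to the median gene. Without a filter 2 slopes changed in m6A-IP and 9 in the difference between fractions. Isoforms tested one by one gave 2675 slope differences, and robust variances 1 slope change in m6A-IP. The most abundant YTHDF2 isoform gave 13.5%, 1.59% and 7.04% remaining (siRNA 1 input, siRNA 2 input, siRNA 2 flow-through). In most of the siRNA 2 libraries behind these means the isoform stood at 0 TPM. The rank correlation of enrichment with the input change for siRNA 1 turned to 0.0156 at a mean of at least 5 TPM and 0.00464 at a pseudocount of 0.1 TPM, where the rank correlation with slope was -0.281.

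With siRNA 1 alone, m6A-IP had 10149 calls and flow-through 3414, and slope changes numbered 1 in input, and relative to the median gene 1 each in input, m6A-IP and flow-through. With siRNA 2 alone m6A-IP had 2827 calls and ratio changes 52. Each siRNA alone was tested with the spread of all libraries of the comparison, so these counts are not separate fits. Without the library with conflicting labels, 5533 genes were called in flow-through and 9063 ratios, and 0 slope changes.

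Leaving out 1 time gave, on deposited TPM, 5920 to 7265 calls in input, 3315 to 4590 in m6A-IP, 4601 to 7023 in flow-through, 10934 to 11156 for enrichment, 5202 to 10090 ratio changes, 3909 to 6342 control slopes, 0 to 7209 slope differences, and slope changes of 0 to 9 in m6A-IP and 0 to 2 in flow-through. Relative to the median gene it gave 213 to 853 ratio changes, 835 to 3098 control slopes, 0 to 1 slope differences, and slope changes of 0 to 6 in m6A-IP and 0 to 1 in flow-through. The rank correlation with slope ran from -0.232 to -0.147.

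Camera on deposited TPM called 5, 8, 5, 9, 3, 9, 5, 10, 4, 5 and 3 lists in the 11 comparisons in the order of the report, and 0 in each with an estimated correlation. With the median gene as scale it called 5 in m6A-IP and 3 for slope changes in flow-through.

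Time as a pairing of libraries was checked by the correlation of same-time deviations, whose medians ran from 0.0706 to 0.286 between siRNAs and from 0.123 to 0.164 between fractions. Not every pair exceeded 0.1, so a pairing by time was not established. Without the block 5008 genes were called in input, 3749 in m6A-IP, 4900 in flow-through, 11129 for enrichment and 9686 for the ratio. With time as a block slope differences numbered 7521, or 24 relative to the median gene, and slope changes 8 in m6A-IP on deposited TPM and 2 in flow-through relative to the median gene. Control input slopes with a time block could not be fitted and were not run.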

Other observations

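The tests in this part were chosen after the results they bear on were seen. In control input the slope of the highest minus the lowest quintile of enrichment was -0.046 per h, which did not pass (adjusted p = 0.05 by exact permutation, and no quintile held in camera with an estimated correlation). A hypothesis was that YTHDF2 accounts for this lower slope. It would then be expected that the slopes of enriched genes rise with YTHDF2 siRNA relative to those of the least enriched. The slope change of the highest minus the lowest quintile was -0.0198 per h, with -0.0272 for siRNA 1 and -0.0121 for siRNA 2, and ran from -0.0278 to -0.0150 when each time was left out. Exact 2-sided permutation of the times gave p = 0.222, with 0.193 for siRNA 1 and 0.329 for siRNA 2, so the value did not lie beyond its spread. Whether YTHDF2 accounts for a lower slope of enriched genes stays open, since 1 control course served both siRNAs and each siRNA has 1 course.

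Across genes, the library with conflicting labels had a root mean square log2 difference of 0.374 from siRNA 1 flow-through at 4 h, 0.582 from siRNA 2 flow-through at 4 h, 0.567 from siRNA 2 flow-through at 6 h and 0.607 from control flow-through at 6 h. It was thus nearest to the siRNA in its title.

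In the m6A-IP, ribosomal RNA of the siRNA 1 libraries ran from 23.7% of TPM at 0 h to 77.3% at 2 h, and the median change of their ratio to flow-through from 0.13 at 0 h to -2.22 at 2 h. Without the siRNA 1 m6A-IP library of 2 h, 5514 genes were called in m6A-IP relative to the median gene and 675 ratios changed.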
